A study of Rattus norvegicus with 16 samples.

How the data were processed

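Bulk RNA was measured in the nucleus basalis of Meynert, a basal forebrain nucleus whose cholinergic neurons project to the cortex, in 16 libraries from Long Evans rats of the ChAT::Cre line, which carries Cre recombinase in cells that express choline acetyltransferase. The labels give an age of at least 70 days, the sex and a stress or control group, with 4 libraries in each of the 4 groups. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these libraries. Replicates were numbered in accession order, and the numbers pair no samples. The series text gives 6 replicates where the samples give 4 per group, and some title numbers are unused. For the 4 stressed female libraries the number in the title differs from the one given with the counts, which changes no comparison of groups but leaves open which title a single library of that group belongs to.

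Per the labels' protocols, libraries were made from total RNA with the NuGen Ovation RNA-Seq System v2, pooled 16 per lane and sequenced as 75 bp paired ends to a stated depth of 130 M (mega) reads per sample. Per the submitters' processing notes, STAR 2.5.2a, bedtools, HTSeq, DESeq and limma were used with the build Rnor_6.0. The deposited values are raw counts per Ensembl gene for 32883 genes. For 13 libraries the files have the layout of HTSeq, with closing lines for reads assigned to no gene. For the other 3, which are female control 4, male stress 1 and male control 4, the counts came from featureCounts 1.6.1 with Ensembl release 92, per the file headers, with a command that counted each mate on its own. Totals were 22.7 to 38.2 M in the HTSeq libraries and 63.1 to 73.8 M in the featureCounts libraries. The lines that name no gene held 44.8% to 64.7% of the entries of the HTSeq files and stayed out of library sizes and tests. No stressed female library was counted with featureCounts, and the 3 featureCounts libraries are too few to be tested alone, so counts of called genes without them stand beside those over all libraries, and values of printed genes whose call ended without them.

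The files hold Ensembl gene identifiers and do not pair them with names. The name table at hand, with 47357 genes, holds no Ensembl identifiers, and 0 identifiers matched. The gene lists, the cell type markers and the rule for named genes fixed before the data were examined could therefore not be applied. Of the called genes with the smallest p, up to 2 identifiers per direction are printed for a comparison, not all with values. Some further genes, chosen after their values were seen, are given by position. Coordinates are 1-based on Rnor_6.0, from the featureCounts files. Groups of genes by chromosome, span and exon number were formed after the data were seen.

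The main test was edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter, which left 14241 genes, and robust quasi-likelihood fits of the 4 group means to all 16 libraries. Contrasts were stress against control in females, in males, their difference and their average, and females against males in controls and in stressed rats. Adjusted p-values are Benjamini-Hochberg values within a contrast, and genes under 0.05 were called. Levels are TMM-normalised counts per M counts (CPM) with mitochondrial counts in the library size, and SE is the standard error of a log2 fold change. Groups of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. Library measures were compared with two-sided exact permutation tests. For 4 against 4 libraries the smallest p such a test can give is 0.0286.

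The fit was tested on simulated data in 5 runs per comparison, each with 200 genes changed in counts drawn for the 14241 genes tested. For stress in females it recovered 27.8% of the 1.5-fold, 63.9% of the 2-fold and 88.8% of the 4-fold changes, with 26 false among 626 calls, and in males 34.3%, 61.5% and 91.5%, with 29 false among 652. For the average over the sexes the shares were 53.7%, 73.4% and 96.7%, with 29 false among 774 calls, and for the difference between sexes 8.06%, 40% and 78.2%, with 20 false among 439. For females against males they were 30.4%, 64.2% and 86.1% in controls, with 39 false among 640 calls, and 29.6%, 62.1% and 87.3% in stressed rats, with 20 false among 615. The false share was thus 6.09% for the control comparison and under 5% for the others. In single runs it reached 8.53% for the control comparison and 7.41% for the average effect. Counts were drawn for each gene on its own from the fit's dispersions, without a tool effect or other structure among libraries. The 200 changed genes exceed the calls in the data, which loosens the adjusted threshold. The recovered shares may therefore be too high for these data, and the false shares need not hold for them. The 5 runs replaced 2 earlier tests of 1 run each with other seeds. In the first of these the false share was above 5% for females, the average and the difference between sexes. The seed was changed because it matched a printed number, and the runs were increased because the share varied between seeds.

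Alternatives were RLE factors, DESeq2 1.42.0, limma voom with quality weights, other low-count filters, only the groups compared, 1 surrogate variable (sva 3.50.0), leaving out each library, leaving out the featureCounts libraries, the counting tool as a covariate, another threshold and no robust shrinkage. Chosen after seeing the data were halved featureCounts counts, nuclear genes only, and leaving out 3 libraries of unusual mapping (female stress 4, female control 2 and male stress 4). Within each group, pairs of HTSeq libraries differed by more than counting error, with a chi-square per degree of freedom of at least 6.88 over the 15 pairs. Separate preparations exceed counting error in any case, so this only argues against repeat runs of 1 preparation.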

Results

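Gene expression in the nucleus basalis of Meynert was compared between stressed and control rats of both sexes, in a study titled for stress, sustained attention and the cholinergic attention system. Each of the 4 groups, female stress, female control, male stress and male control, held 4 libraries. Mitochondrial genes took 64.2% to 82.5% of the counts, which left 5.86 to 22.6 M nuclear counts per library. The 2 most counted genes lay at MT 1094 to 2664 and MT 68 to 1025, and took 52.2% to 69.6% of a library. In vertebrates this part of the mitochondrial genome holds the ribosomal RNA genes.

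**Figure D1:**
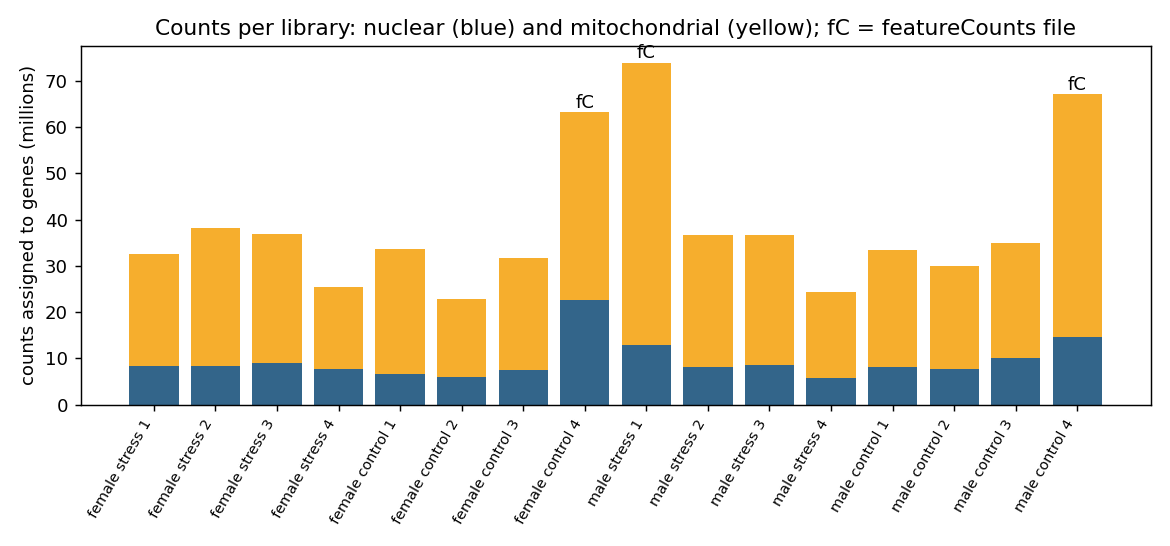
Bars give the counts assigned to genes in each of the 16 libraries, split into nuclear (blue) and mitochondrial (yellow) genes, with fC above the featureCounts libraries. The featureCounts libraries reach 63.1 to 73.8 M, above the 22.7 to 38.2 M of the HTSeq libraries.

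The 48 Y-linked genes served as a check of the sex labels. Scaled to nuclear counts, they gave 8.28 to 11.4 CPM in the 8 female libraries and 281 to 326 in the 8 male libraries. All 16 libraries matched their labelled sex.

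Stress on average over the sexes tests the mean of the effects in the 2 sexes, which a gene can also pass by a change mainly in 1 sex. By edgeR's quasi-likelihood test, 33 genes rose and 15 fell of 14241. Without the 3 featureCounts libraries 29 genes were called, among them 24 of the 33 that rose and 3 of the 15 that fell. ENSRNOG00000003977 (chromosome 10, 16970626 to 16973418) rose 3.91-fold (log2 fold change 1.97, SE 0.11, adjusted p = 7.85e-12). Its level was 26.5 ± 1.7 CPM (SD, n = 4) in stressed and 6.57 ± 1.8 CPM in control females, and 20.3 ± 2.6 against 5.30 ± 0.56 CPM in males. ENSRNOG00000007830 (chromosome 4, 168752133 to 168755023), a gene with 1 annotated exon, rose 9.47-fold (log2 fold change 3.24, SE 0.18, adjusted p = 1.3e-10). It went from 1.16 ± 0.39 to 13.0 ± 2.4 CPM in females and from 1.64 ± 0.34 to 13.3 ± 4.7 CPM in males (SD, n = 4). In both genes all stressed libraries lay above all control libraries of their sex.

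**Figure D2:**
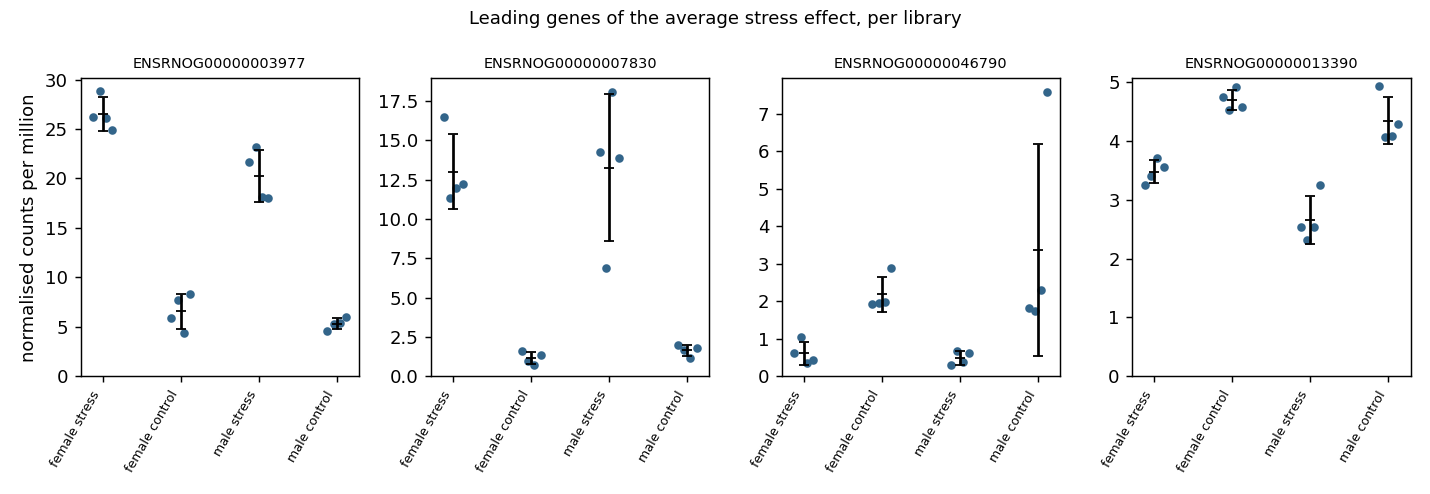
Each panel gives the normalised level (CPM) of 1 gene in the 4 libraries of each group, with points for libraries and bars for mean and SD. ENSRNOG00000003977 and ENSRNOG00000007830 are higher in stressed rats, and ENSRNOG00000046790 and ENSRNOG00000013390 are lower, with 1 male control library of ENSRNOG00000046790 at 7.57 CPM.

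ENSRNOG00000046790 (chromosome X, 113002150 to 113018073) fell by 2.35 on the log2 scale (SE 0.32, adjusted p = 0.00036). Without the 3 featureCounts libraries its log2 fold change was -1.76 (adjusted p = 0.000461). ENSRNOG00000013390 (chromosome 4, 127164453 to 127177477) fell by 0.57 on the log2 scale (SE 0.11, adjusted p = 0.0137), from 4.69 ± 0.17 to 3.48 ± 0.20 CPM in females and from 4.34 ± 0.40 to 2.65 ± 0.41 CPM in males (SD, n = 4). Without the featureCounts libraries its log2 fold change was -0.57 (adjusted p = 0.0734). The log2 fold changes of the 33 genes that rose ran from 0.45 to 3.24, and those of the 15 that fell from -2.35 to -0.39. A pair of 1-exon genes on chromosome 17, at 43639749 to 43640387 and 43734461 to 43735120, rose by log2 fold changes of 0.88 and 0.89. The second was not called without female stress 2 or male control 4, with adjusted p up to 0.0550. Of the 15 genes that fell, 4 lay on chromosome X, and 0 of the 33 that rose did. Of these 4, only ENSRNOG00000046790 was called without the featureCounts libraries. All 48 had the same sign in females and males, and 21 had every stressed library beyond every control library in both sexes, as their choice by the average effect favours. Of the 48 genes, 4 overlap another annotated gene and their counts are uncertain.

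Stress in females raised 9 genes and lowered 0, with 923 genes at an unadjusted p under 0.05 by edgeR. DESeq2 called 26 and limma voom 12. ENSRNOG00000003977 rose 4.00-fold (adjusted p = 1.42e-08) and ENSRNOG00000007830 rose 11.0-fold (adjusted p = 5.68e-08). A gene on chromosome 20, at 10668411 to 10680283, rose by a log2 fold change of 1.47 (SE 0.19, adjusted p = 0.00015), from 2.00 ± 0.49 to 5.49 ± 0.26 CPM (SD, n = 4). In males its log2 fold change was 0.62 (adjusted p = 0.337), and the difference between sexes, 0.86 (SE 0.26), did not pass edgeR's quasi-likelihood test (adjusted p = 1.0). Without the featureCounts libraries, which in females leaves out 1 control, 14 genes were called, 9 of them shared. Among those not shared, ENSRNOG00000046790 on chromosome X fell (log2 fold change -1.67, adjusted p = 0.0459 by edgeR).

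Stress in males raised 16 genes and lowered 1. ENSRNOG00000003977 rose 3.81-fold (adjusted p = 3.48e-08) and ENSRNOG00000007830 rose 8.11-fold (adjusted p = 3.41e-07). ENSRNOG00000046790 fell by 2.85 on the log2 scale (SE 0.46, adjusted p = 0.00718), from 3.36 ± 2.8 to 0.487 ± 0.18 CPM (SD, n = 4). A gene on chromosome 13, at 50913180 to 50916982, rose by a log2 fold change of 2.30 (SE 0.33, adjusted p = 0.00136). It went from 0.537 ± 0.28 to 2.62 ± 0.77 CPM (SD, n = 4), with only 7 to 30 counts in the male controls. In females, where it was not called, it went from 1.09 ± 0.49 to 2.94 ± 0.48 CPM, and it was called on average over the sexes. A gene on chromosome 7, at 141370491 to 141377928, rose from 21.3 ± 2.8 to 36.4 ± 6.1 CPM (SD, n = 4; log2 fold change 0.77, adjusted p = 0.0116). Without the featureCounts libraries its log2 fold change was 0.73 (adjusted p = 0.0943), and adjusted p was up to 0.102 without male stress 1 or 2 or male control 1 or 3, which ended the call. In the HTSeq libraries alone 5 genes were called in males, 4 of them shared, and ENSRNOG00000046790 had a log2 fold change of -1.84 (adjusted p = 0.0772). It was not called without male stress 1 or 3 either, with adjusted p up to 0.0660. Of the genes that rose, 7 were called in both sexes, against 0.0101 for independent lists of these sizes. Both lists come from 1 fit that shares the spread of each gene, which favours overlap. With each sex fitted alone 5 genes rose in both, all among the 7, against 0.0118 for independent lists. Without the featureCounts libraries 4 genes rose in both sexes, 3 of them among the 7, against 0.00333 for independent lists, and without female stress 2 also 4, all among the 7.

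The difference of the stress effect between sexes was called for 0 genes by edgeR, with 571 at an unadjusted p under 0.05. DESeq2 called 1 and limma voom 0. Among the 48 genes called on average, tested alone, 0 differed between sexes, with a smallest adjusted p of 0.136. The log2 fold changes of females and males had a Pearson correlation of 0.16 and a Spearman correlation of 0.17 across the 14241 genes, which are not independent replicates. The Pearson value was 0.088 without the featureCounts libraries, 0.070 without male control 4 and 0.39 over genes with a mean of at least 10 CPM.

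**Figure D3:**
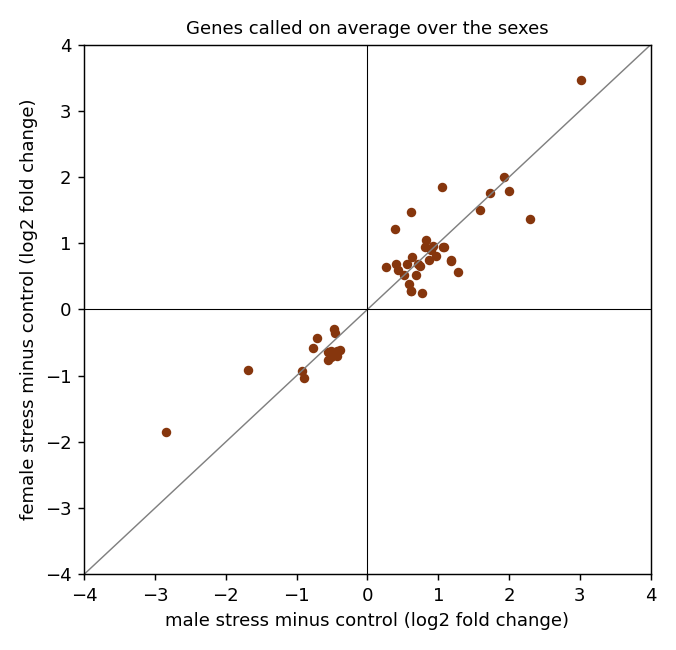
Points are the 48 genes called on average over the sexes, with the log2 fold change of stress in males on the horizontal and in females on the vertical axis, and the grey line marks equality. All 48 lie in the quadrants of equal sign, with a median ratio of female to male log2 fold change of 0.996.

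Females and males were compared within controls. In controls 6 genes were higher and 10 lower in females, and 12 of these 16 lay on X or Y. The Y-linked ENSRNOG00000057231 (1217800 to 1238420) had 0.138 ± 0.043 CPM in female and 33.2 ± 4.0 CPM in male controls (SD, n = 4; adjusted p = 2.94e-20). ENSRNOG00000060048, also on Y (914045 to 933699), had 0.0821 ± 0.034 and 15.9 ± 1.2 CPM (adjusted p = 1.77e-18). On X, ENSRNOG00000051257 (74333329 to 74337975) had 121 ± 44 CPM in female and 0.952 ± 0.63 CPM in male controls (adjusted p = 7.6e-08), and ENSRNOG00000055225 (74325012 to 74325079) had 7.71 ± 3.5 and 0.0406 ± 0.028 CPM (adjusted p = 3.63e-11). Both lie inside ENSRNOG00000037911 on the opposite strand, which was also called, and the sources used here do not say that counting used strand, so reads of these genes cannot be told apart. The chromosome 7 gene named for males was higher in female controls, at 39.9 ± 6.9 against 21.3 ± 2.8 CPM (SD, n = 4; log2 fold change 0.91, SE 0.14, adjusted p = 0.000988), a comparison that uses the same male controls. In the HTSeq libraries alone 10 genes were called, all 10 among the 16.

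In stressed rats 5 genes were higher and 8 lower in females, and 12 of these 13 lay on X or Y. These 12 were also called in controls, and 3 of them are the overlapping genes ENSRNOG00000051257, ENSRNOG00000055225 and ENSRNOG00000037911. ENSRNOG00000037911 (chromosome X, 74304292 to 74345507) had 39.2 ± 8.7 CPM in stressed females and 0.601 ± 0.20 CPM in stressed males (SD, n = 4; log2 fold change 6.04, adjusted p = 1.9e-08). The autosomal gene, on chromosome 8 at 58486078 to 58542844, was lower in females, at 129 ± 5.3 against 191 ± 16 CPM (log2 fold change -0.57, SE 0.11, adjusted p = 0.0334). Its call ended without any of 9 single libraries, each stressed female, male stress 2, 3 or 4, female control 3 and male control 1, with adjusted p up to 0.231 without male stress 2. In the HTSeq libraries alone 14 genes were called, 13 of them shared.

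Gene groups by position were tested with camera. The 15 mitochondrial genes of 200 bases or more had a median log2 fold change of 0.43 with stress in males, with 0 of 15 called alone (adjusted p = 4.85e-07 by camera, adjusted p = 0.463 with an estimated correlation). The mitochondrial share of counts was 78.2% ± 3.0 in stressed and 74.9% ± 3.1 in control males (SD, n = 4; two-sided exact permutation p = 0.2). The 513 genes tested on chromosome X had a median of -0.07 with stress in males, with 0 higher and 1 lower (adjusted p = 0.0126 by camera, adjusted p = 0.214 with an estimated correlation).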

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

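Among the tests below, the splits for the average stress effect, for the full counts of both sex comparisons and for the correlation were set before their results were seen. So were the covariate tests of reads outside genes and of the mitochondrial share, but not the criterion for the counting tool as a covariate. The other tests were chosen only after the result was seen.

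The first pattern is the 48 genes called for stress on average over the sexes (33 higher, 15 lower). In 1 of 100 relabelings of stress within sex, the real one, as many genes were called, and the highest of the others gave 1. This argues against chance but does not exclude it, as 1 of 100 is the smallest share these relabelings can give. A structure among libraries that goes along with the stress groups would not be seen by this test. The tables argue against the counting tool as the whole cause. With the tool as a covariate the median of the 33 genes that rose kept 101.3% of its fold change (lower quartile 99.0%) and 31 stayed called. The median of the 15 that fell kept 95.2% (lower quartile 89.2%) and 9 stayed called, with the median log2 fold change at -0.55 (median SE 0.12) against -0.60 (median SE 0.13). The fitted tool difference made up -2.71% to 8.24% of the fold changes of the 15, and 0 of the 48 genes were called for it. The share of featureCounts libraries, stressed minus control, was only -0.125 on average over the sexes. By design this keeps the tool's part, and the change under the covariate, small. With only 3 featureCounts libraries a tool difference can also be missed. Without the 3 featureCounts libraries 24 of the 33 stayed called, and the median gene kept 98.7%. Of the 15 that fell 3 stayed called, and the median gene kept 90.4% (61.6% to 111%), at -0.57 (median SE 0.13). When 1 other library was left out of each of the same 3 groups, in 27 sets, 1 to 12 of the 15 stayed called, so the lost calls are no more than fewer libraries give. The median share kept in those sets was 96.5% to 112%, so part of the size of these falls stays open to the 3 libraries. With the share of reads outside genes as a covariate in the HTSeq libraries the median gene kept 99.7% of its fold change, and the 27 of the 48 genes that were called there stayed called. Stressed minus control, this share differed by 4.46 points in females and by -5.77 points in males. These nearly cancel in the average, so this test could hardly change the fold changes and says little. In males the share was 13.1% to 14.0% in stressed and 16.6% to 22.0% in control HTSeq libraries. The male calls were not tested with it. With the mitochondrial share as a covariate the median gene kept 99.4% (lower quartile 93.0%), but only 34 of the 48 calls stayed (28 higher, 6 lower), with SE 1.04 times as large for the median gene. Stressed minus control, the mitochondrial share differed by 0.81 points in females and by 3.33 points in males. Its SD within groups was 2.97 to 6.83 points. Such small differences keep the change under the covariate small, so the test is only weak evidence against this share as the whole cause. A different mix of dissected cells was not tested, because no gene names were at hand, so a response of the nucleus to stress remains a hypothesis.

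ENSRNOG00000046790 on chromosome X stood apart in male control 4, at 7.57 CPM against 1.75 to 2.31 CPM in the other male controls, and in female control 4, at 2.87 CPM against 1.92 to 1.98 CPM. Both libraries were counted with featureCounts. Male stress 1, also counted with featureCounts, had 0.303 CPM, the lowest of the stressed males, which reached 0.659 CPM. The featureCounts libraries were thus not all high for this gene. Without the 3 featureCounts libraries the average log2 fold change was -1.76 (adjusted p = 0.000461 by edgeR), against -2.35 with them. The counting tool therefore does not account for the whole fall, though it may account for part of its size, and stress remains an open explanation.

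Other libraries stood apart from their group. Male control 4 had 67.0 M counts against 30.0 to 34.9 M in the other male controls, and was counted with featureCounts. Female stress 4 had 31.2% of reads outside genes against 15.0% to 17.3%. ENSRNOG00000007830 had 16.5 CPM in female stress 1 against 11.3 to 12.2 CPM. In female stress 4, ENSRNOG00000051257 had 197 CPM against 128 to 136 CPM, and ENSRNOG00000037911 had 52.1 CPM against 33.9 to 36.0 CPM. In male control 1, ENSRNOG00000037911 had 0.481 CPM against 0.761 to 0.800 CPM. In all 8 of 50 groups tested had such a library, where chance gives about 1 in 20 of independent groups. These groups are not independent, so the excess cannot be weighed. ENSRNOG00000051257 and ENSRNOG00000037911 overlap and stood apart in the same library, and the total of male control 4 goes with its counting tool. The genes screened were limited to called ones after a first, wider screen had been seen, in which 1 further group, of a gene not called, had such a library. The screen needed 4 values, so groups with a featureCounts library were not screened for reads outside genes or not aligned. In these groups female control 2 had 40.8% of reads not aligned, against 13.8% and 14.6% in the other HTSeq female controls. Male stress 4 had 38.8%, against 13.5% and 14.0% in the other HTSeq stressed males.

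For 2 gene groups the stress effect differed between sexes by camera at the preset correlation. The 15 mitochondrial genes had a median difference, female minus male, of -0.38 (adjusted p = 0.00178, adjusted p = 0.545 with an estimated correlation). The 1425 genes of the longest spans had a median difference of 0.08 (adjusted p = 0.0103, adjusted p = 0.173 with an estimated correlation).

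Other splits of the same libraries were counted for each remaining comparison. For stress in females 1 of 35 splits, the real one with 9 genes, reached that count, and the highest other gave 8. As 1 of 35 is the smallest share these splits can give, the count alone is weak evidence against chance. For stress in males the real split of 35 was the 1 with as many as 17 genes, and the highest other gave 1. For females against males in stressed rats it was again 1 of 35, with 13 genes against 0. For controls 2 of 35 splits gave as many as the real 16 genes, so the count alone cannot exclude chance. For the 12 of these genes on X or Y only 1 of 35 splits, the real one, gave as many, with at most 1 such gene in the others. Of these 12, 7 lie on Y, whose counts had already matched the sex labels, so this outcome was close to fixed beforehand. It therefore adds little against chance, but all 12 were called in stressed rats too. For the other 4 genes, 3 of 35 splits gave as many. The other split of the full count, with 56 genes, parted replicates 1 and 2 of both sexes from replicates 3 and 4, which points to a structure of the control libraries that the labels do not give, and both featureCounts controls lay on one side of it. For the difference between sexes the real count was 0, which all 100 relabelings reach whatever the data, with up to 5 in the others, so this test says nothing about chance. For the Pearson correlation of 0.16 between sexes 4 of 100 were as high, with a highest other of 0.20, and for the Spearman correlation of 0.17 7 of 100, with 0.24. The 2 measures lie on either side of 5 in 100, so the correlation gives little against chance.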

How the results depend on the processing

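No call among the 48 genes of the average effect changed sign in any alternative, of which there were 28 (27 for 1 gene), and 21 of the 48 were called in all 28. ENSRNOG00000003977 and ENSRNOG00000007830 stayed past the threshold in every alternative run, in females, in males and on average. ENSRNOG00000046790 lost its call in males in 5 of 29 alternatives, with adjusted p up to 0.0772. DESeq2 called 26 genes for stress in females, 31 in males, 1 for the difference between sexes, 101 on average and 27 between control sexes. Without a low-count filter these counts were 105, 88, 36, 207 and 54, with 105 between stressed sexes. Without the featureCounts libraries they were 14 in females, 5 in males, 29 on average and 10 between control sexes. With 1 surrogate variable 14 genes were called in females, and with only the groups compared 27 in males. Leaving out 1 HTSeq library from each of the same 3 groups instead, in 27 sets, gave 5 to 10 in females, 4 to 11 in males, 18 to 54 on average, 9 to 16 between control sexes and 10 to 13 between stressed sexes. Fewer samples alone thus give such counts in males, on average and between control sexes, but not the 14 in females or the 14 between stressed sexes. The cause of the other shifts was not tested. Leaving out 1 library gave 7 to 21 genes in males and 28 to 56 on average. In males the count moved by over 1.5 times without male stress 1 (7), 2 (11) or 3 (10) and male control 1 (9), 2 (11) or 3 (9). On average it did so without female stress 2 (28), female control 2 (31), male stress 2 (31) or 4 (29) and male control 4 (28). The correlation between sexes was 0.39 over genes with a mean of at least 10 CPM, and 0.070 without male control 4. It was taken over the genes of the main test, a choice made after seeing the values. With the filter run anew it was 0.045 to 0.15 when 1 library was left out and 0.058 without the featureCounts libraries. Without the 3 libraries of unusual mapping, chosen after seeing the data, 8 genes were called in females, 13 in males, 34 on average and 0 for the difference. Tests of the fixed gene lists and named genes were not run, for want of gene names.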

Other observations

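The tests below were chosen only after the results were seen, except that of a bias by span, set before its value was seen.

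Sex differences outside the sex chromosomes were few. In controls a gene on chromosome 13 at 87966758 to 88003035 was lower in females, at 25.8 ± 2.9 against 41.9 ± 3.7 CPM (SD, n = 4; adjusted p = 0.00651 by edgeR). Its log2 fold change was -0.70, and -0.68 without the featureCounts libraries (adjusted p = 0.0818), and adjusted p was up to 0.0559 without female control 2 or male control 1. On X, 2 genes at 63268037 to 63292092 and at 4806277 to 4945944 were higher in females by log2 fold changes of 0.69 and 0.59 in controls and of 0.61 and 0.85 in stressed rats. The call of the first in stressed rats ended without female stress 3 or male stress 3, with adjusted p up to 0.0710. The call of the second in controls ended without any 1 of the 8 control libraries, with adjusted p up to 0.168, and without the featureCounts libraries it had 0.331. Neighbouring pairs within 200 kb numbered 1 among the 48 genes called on average, against a mean of 0.495 in random lists (permutation p = 0.39).

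A hypothesis formed after seeing the data is that stress raised short genes. The 33 genes that rose had a median genomic span of 10138 bases, against 24730 in random lists matched on expression, at the 0.09 percentile of these lists. Over the genes not called, the Spearman correlation of fold change and span was 0.0087, and 58 of 100 relabelings were as low. This gives no sign of a bias by genomic span between stressed and control libraries in the average effect. A bias by exon length was not tested. A bias by span within the spread of the relabelings (SD 0.0525) would not be seen. The 15 genes that fell had a median span of 11218 bases, at the 2.93 percentile of their matched lists, so that a readier call of changes in short genes may explain part of the pattern and cannot be told apart from it with so few genes.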
